A study of Homo sapiens
Mus musculus and Homo sapiens with 2 samples.

How the data were processed

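The series held 2 samples measured by sci-fate, a single-cell RNA assay that marks RNA made during a short window. Cells took up 4-thiouridine (S4U), a uridine analog, and fixed cells were then treated with iodoacetamide, which alters the S4U bases so that they read as base changes in the cDNA. The first sample was a mixture of HEK293T, a human embryonic kidney line, and NIH/3T3, a mouse fibroblast line, given 200 µM S4U for 6 h. The second was A549, a human lung adenocarcinoma line, exposed to dexamethasone, a synthetic glucocorticoid, for 0, 2, 4, 6, 8 or 10 h, with 200 µM S4U during the last 2 h. The treatment protocol gives the dexamethasone dose as 100 nM, and a further label of the A549 sample gives 101 nM. The mixture's label also lists dexamethasone, which the protocol assigns to A549, so the mixture was not treated here as exposed to it.

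Per the labels, the authors' processing named Trim Galore 0.4.1, STAR 2.5.2b, SAMtools 1.3 and Picard 1.105 with the hg19 and mm10 builds, and gave no settings. The deposited gene matrices hold raw counts per gene and cell, without normalization. One matrix of each sample holds all counts (whole RNA), and the other holds the counts that the authors called newly synthesised (new RNA). How duplicate reads were collapsed and how new molecules were called are not given in the sources used here. New counts never exceeded the whole counts of the same gene and cell, so whole minus new counts were computed and are called pre-existing RNA. This fraction also holds any new molecules that were not called new, and how many is unknown. Per the file headers, the cell annotation gives exon, intron and total values of each cell. The exon and intron values of the mixture are headed as reads. The annotation holds the authors' call of each mixture cell as human, mouse or both species, its labelling group, and the dexamethasone time of each A549 cell. The deposited annotation also gives a fraction per mixture cell, whose median in labelled cells was 49.95% in HEK293T and 30.8% in NIH/3T3, below the new over whole counts used here, and the authors' doublet score per A549 cell, whose highest value was 0.191. Whether cells had been left out on that score before deposit is not given in the sources used here.

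The mixture's whole matrix held 6307 cells, of which 6305 were in both matrices. The annotation gave 100 cells of the whole matrix no labelling group and no fraction, and 6207 cells with a group were in the comparisons. All 7404 A549 cells were used. Human and mouse counts were told apart by gene identifier. Each line and labelling group, and each dexamethasone time, was 1 culture as far as the labels show, and cells were never counted as replicates. Here "culture" stands for all cells of 1 time or labelling group.

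Whole counts per A549 culture ran from 28870594 to 43084614 and new counts from 5865326 to 9718958. Labelled HEK293T cells held 6725232 whole counts and labelled NIH/3T3 cells 3104845. Shares of counts or cells carry exact Clopper-Pearson 95% intervals, and ratios of counts pooled over the 5 treated cultures to those at 0 h carry exact intervals from the same method. These cover counting error only, not differences between cultures. The floor for a count of 0 was 3 counts in the 0 h culture.

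Dexamethasone was tested on counts summed over the cells of each time, with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, TMM normalization and filterByExpr at its default minimum count of 10. The first model set the 0 h culture against the 5 treated cultures, with 4 residual degrees of freedom, in whole and in new RNA. In this model the lone 0 h culture is assumed to vary like the treated ones, and their spread includes change over time. A second model tested a linear slope over the 5 treated times, with 3 residual degrees of freedom. A further model tested whether new RNA changed more than pre-existing RNA, with a term for each culture and 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. Standard errors of fold changes were taken from the fitted fold and its F statistic. On simulated data with a dispersion of 0.015, the test of treated against 0 h recovered 86.6% of 2-fold changes in whole RNA and 79.1% in new RNA, and 19.4% of 1.5-fold changes in each. Each change simulated for that test was the same at all 5 treated times. Changes that vary over time also widen the spread, so their recovery may be lower. The slope test recovered 35.0% of slopes of 0.1 log2 units per hour in new RNA and 37.0% in whole RNA. The slope models fitted to the data had less spread than this simulation. The square root of their dispersion was 0.0682 in new and 0.0639 in whole RNA, so the simulated recovery may be too low for them. In a separate simulation, with a lower dispersion and variation between cultures shared by both kinds of RNA, the test of new against pre-existing RNA recovered 79.1% of 2-fold differences. There each difference was the same at all 5 treated times and pre-existing RNA did not change, so this recovery may be too high for the data.

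The gene lists, the comparisons, the rule for named genes and the alternatives were fixed before the data were examined, except that tests of lists for slopes, list medians by time, matching on gene span, Pearson correlations, new shares of cell cycle classes by time and the correlation of A549 with NIH/3T3 were added later. The lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the data. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Lists overlap, and some hold the same gene.

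The new share of a gene was its new over its whole counts, pooled over the labelled cells of a line or over all A549 cells, for protein-coding genes with at least 1000 whole counts. A list's median share was ranked among 10000 random lists of the same size, drawn with replacement from genes in the same of 10 bins of expression. In a further ranking they matched in 5 bins of expression and 5 bins of gene span as well. Spans came from the GENCODE release 29 annotation on GRCh38, another build than the authors used, so they serve as a property of genes matched by identifier and no positions are given. They covered 99.5% of the HEK293T genes and 99.2% of the A549 genes, and none were used for mouse genes. For scores of single cells, A549 cells were thinned at random to 2700 new or 15500 whole counts, and cells with fewer were left out. The glucocorticoid score was the number of counts on glucocorticoid-induced genes. Cell cycle classes used alternate genes of an S-phase and a G2/M list. Each score was the mean log of 1 plus the count, less its median over cells and divided by its SD, and a cell took the class of its larger score where that was above 0.5. Other cells were called low, and the remaining genes of the lists served to describe the classes.

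By the rule for named genes, those named for dexamethasone were the 10 protein-coding genes with the largest fold up and the 10 down in whole and in new RNA, among those past the threshold, on the same side of 0 h at all 5 treated times and with at least 500 counts. For slopes they were the 5 largest each way, for lists up to 4 members with the largest fold, and for new shares the 10 highest and 10 lowest genes of each line. FKBP5, TSC22D3, PER1 and NR3C1 were always included. Some genes that the rule names are not reported here. Alternatives covered RLE size factors, DESeq2 1.42.0 in place of edgeR, no low-count filter, removal of ribosomal protein and mitochondrially encoded genes, equal numbers of cells per time, removal of the 10% largest cells, and leaving out each treated culture in turn. For shares they covered the median over cells, protein-coding genes only, no mitochondrially encoded genes, a minimum of 200 counts, subtraction of the background in iodoacetamide-only cells, and the 0 h culture alone. For scores they covered unthinned counts and other thresholds. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for everything outside R. Raw sequencing reads were not used here.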

Results

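Newly made and total RNA were counted in single cells of 3 established lines after metabolic labelling with S4U. In the mixture, 913 HEK293T and 425 NIH/3T3 cells had both the S4U label and the iodoacetamide treatment. Cells of the same lines had iodoacetamide only, S4U only or neither, which gives the background of the new RNA call. The A549 sample held 1151 cells at 0 h of dexamethasone, 1189 at 2 h, 1045 at 4 h, 1404 at 6 h, 1169 at 8 h and 1446 at 10 h, with a median of 27080 whole and 5539 new counts per cell. There was 1 culture per line and labelling group and 1 per dexamethasone time, without replicates, and no unlabelled A549 cells were used here, so the background in that line is unknown.

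The mixture asked whether new RNA can be told from older RNA. In labelled HEK293T cells 54.5% of counts were new (exact 95% interval 54.46 to 54.53), and the median cell had 54.1% (quartiles 49.7 and 58.5). NIH/3T3 cells had 33.0% (32.93 to 33.03), with a median cell of 32.9% (30.02 to 35.6). The background was 1.25% in HEK293T cells with iodoacetamide only and 0.891% in those with neither treatment, and 1.09% and 0.736% in NIH/3T3. Over all mitochondrially encoded genes together, 17.9% of counts were new in HEK293T and 14.4% in NIH/3T3. The 5 mitochondrially encoded mRNAs with at least 1000 counts in NIH/3T3 had 35.0% to 44.3%, so the 14.4% does not describe them. Over all protein-coding genes the NIH/3T3 share was 42.0%. Intronic reads of the annotation, which come largely from unspliced transcripts, were 80.1% new in HEK293T against 42.4% of exonic reads, and 48.1% against 31.4% in NIH/3T3. Cells that the authors called human or mouse held 99.3% to 99.6% counts of their own species, which that call largely fixes, and 166 of 6207 cells (2.67%, 2.29 to 3.11) were called as both species.

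**Figure D1:**
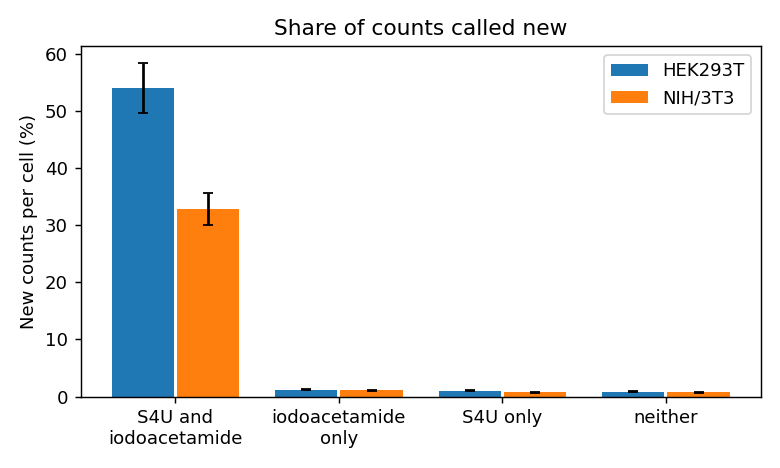
Percent of counts called new in the median cell of HEK293T and NIH/3T3, by labelling group, with error bars at the quartiles over cells. The cells with both S4U and iodoacetamide sit at 54.1% and 32.9%, and the other groups near the background.

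Genes differed widely in the share of their RNA made during labelling. Across 1524 protein-coding genes in HEK293T the median share was 55.2%, with a 10th percentile of 17.4% and a 90th of 84.0%. The highest share was that of RLIM (ENSG00000131263.8), a ubiquitin ligase gene, with 89.5% (87.5 to 91.4). PANK3 had 89.2%, AMD1, which encodes an enzyme of polyamine synthesis, 89.1%, the kinase gene DYRK1A 88.3%, DACH1 88.2%, and the splicing regulator gene MBNL1 88.2%. PRR4, ETNK1 and FOXP2 followed with 88.1%, 88.0% and 88.0%. At the low end stood GPS2 (ENSG00000132522.11) with 1.40%, BSG 5.47%, NT5DC2 7.18%, PRDX2 7.60%, RPL36 7.68%, the actin-binding PFN1 7.95%, SSR4 9.50%, TAGLN2 9.68%, RPS21 10.1% and RPLP2 10.4%. COX6A1 (ENSG00000111775.2), chosen after its value was seen, was the 1 HEK293T gene with over 10% new counts in iodoacetamide-only cells, at 10.6%, against a median background of 1.14%.

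Ribosomal protein mRNAs had a median share of 14.9% in HEK293T (70 members), lower than all 10000 random lists of like expression, and 15.9% in NIH/3T3 (41 members), again lower than all of them. In HEK293T, 9 glycolysis genes had a median of 14.3% (percentile 1.28 among random lists), 9 actin cytoskeleton genes 13.0% (percentile 0) and 5 NRF2 targets, which act against oxidative stress, 14.4% (percentile 0.05). In NIH/3T3, 4 glycolysis genes had 17.8% (percentile 13.8) and 10 actin cytoskeleton genes 30.8% (percentile 33.3). S-phase genes had 68.4% in HEK293T (percentile 71.5, and 93.8 with span matched) and G2/M genes 57.9% (59.2 and 97.7). In NIH/3T3 the median was 54.8% over 6 G2/M genes (percentile 99.3), 57.3% over 3 S-phase genes (99.1), 41.4% over 5 mitochondrially encoded mRNAs (98.0) and 16.7% over 8 fibroblast markers (6.80). The highest mouse genes were Mbnl1 (ENSMUSG00000027763.13) with 64.7% (62.7 to 66.7), Ipo7 63.9%, Scd2, a fatty acid desaturase gene, 62.4%, Erbin 62.0%, Ddx5 61.9%, Anln 60.3%, Zfpm2 60.0%, Hmga2 60.0%, Nfat5 59.8% and Emp1 59.5%. The lowest were Cmss1 with 4.66%, Zc3h7a 6.99%, the matrix gene Bgn 7.37%, S100a11 9.73%, Ftl1 10.2%, Cox4i1 10.3%, Rps9 10.3%, Rpl3 10.5%, Rpsa 11.03% and Lgals1 11.2%. Across 204 genes of the same symbol the HEK293T and NIH/3T3 shares had a Spearman rho of 0.851 and a Pearson r of 0.799. Genes are not independent replicates, so these and all list percentiles describe these libraries only. Longer gene spans went with higher shares in HEK293T, with a Spearman rho across genes of 0.693.

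In A549, where labelling lasted 2 h, 21.2% of counts were new, and the 6 cultures ran from 20.3% to 22.6%. Intronic counts were 66.6% new against 12.9% of exonic counts. The median gene had 25.6% over 10687 genes. SOCS3 (ENSG00000184557.3), a feedback inhibitor of cytokine signalling, had the highest share with 90.4% (88.9 to 91.8), followed by the stress gene DDIT4 with 89.6%, ID3 87.3%, the phosphatase gene DUSP1 86.7%, ID1 86.6%, ZNF92 86.2%, TIPARP 85.9%, TRIB1 85.2%, YOD1 85.2% and PIM3 85.1%. NGB (ENSG00000165553.4) had 0.151%, from 2 new of 1327 counts, FAM166A 0.390%, ATRNL1 0.527%, GPS2 0.587%, VTN 0.706%, AC087645.1 0.824%, HYI 0.834%, AC119673.1 0.865%, the secreted peptide gene TFF1 0.912% and SNX32 0.921%. These lowest shares lie below the background in iodoacetamide-only cells of the other lines, 1.25% in HEK293T and 1.09% in NIH/3T3. They may therefore be at the floor of the call, and do not by themselves show RNA that was not made during labelling. Immediate early genes had a median of 75.2% (18 members) and short-lived regulators 77.4% (28 members), both above all random lists matched on expression or also on span. Glucocorticoid-induced genes had 70.3% (32 members), also above all of them, over cultures most of which had dexamethasone. Circadian clock genes had 44.4% (percentile 93.6, and 87.5 with span matched), p53 targets 36.7% (91.7 and 99.8) and NRF2 targets 13.4% (40.1 and 42.3). Low medians included those of ribosomal protein genes with 5.95% (percentile 0, and 0.31 with span matched), 8 fibroblast markers 6.05%, A549 markers 6.67%, actin cytoskeleton genes 6.93% and glycolysis genes 8.38%. Unfolded protein response genes had 10.6% (percentile 0.33, and 4.16 with span matched), heat shock genes 10.8% (16.7 and 68.7) and epithelial junction genes 11.1% (4.32 and 1.56). Interferon response genes had 12.9% (3.45 and 3.3) and cholesterol synthesis genes 16.2% (1.06 and 24.3). Across 1497 genes the A549 and HEK293T shares had a Spearman rho of 0.930 and a Pearson r of 0.841, and the rho was 0.864 with span removed. For A549 and NIH/3T3 these were 0.754 and 0.575 over 260 genes.

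The A549 time course asked which genes respond to dexamethasone, and whether new RNA shows it apart from older RNA. In whole RNA, TSC22D3 (ENSG00000157514.12), a glucocorticoid-induced leucine zipper gene, rose by a log2 fold of 4.49 ± 0.49 (SE; adjusted p = 0.00819) over the 5 treated cultures against 0 h. FGD4 (ENSG00000139132.10) rose by 4.03 ± 0.17 (adjusted p = 0.000124), and the clock gene PER1 (ENSG00000179094.9) by 3.08 ± 0.20 (adjusted p = 0.000682). The lipoprotein lipase inhibitor gene ANGPTL4 rose by 3.58, the prostaglandin receptor gene PTGER4 by 3.09, ARRB1 by 2.96, SDK1 by 2.83, the transcription factor gene KLF9 by 2.82, SYBU by 2.82 and POU5F1 by 2.79. GDF15, a stress-induced cytokine gene, fell by 2.46 ± 0.31 (adjusted p = 0.0161), and the immediate early gene IER3 (ENSG00000137331.11) by 1.88 ± 0.20 (adjusted p = 0.0069). The other large falls were C6orf141 −2.19, ENC1 −1.79, the nuclear receptor gene NR5A2 −1.73, THSD1 −1.50, IER5L −1.47, PLK2 −1.47, the AP-1 gene FOSL1 −1.46 and ZIC2 −1.23. FKBP5 (ENSG00000096060.10), a chaperone of the glucocorticoid receptor, had a log2 fold of 3.45 ± 0.66 in whole RNA (adjusted p = 0.0702), and without the 2 h culture 3.65 (adjusted p = 0.000242). NR3C1, the receptor gene, had −0.41 ± 0.11 (adjusted p = 0.173), and without the 2 h culture adjusted p = 0.0333. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 138 genes rose and 63 fell of 22894 in whole RNA. Leaving out 1 culture changed these counts to 931 and 669 without 2 h, 61 and 25 without 4 h, 57 and 18 without 6 h, 58 and 18 without 8 h, and 113 and 36 without 10 h. DESeq2 gave 557 and 229, and edgeR without a low-count filter 302 and 149. ANGPTL4 had adjusted p = 0.0617 without 4 h, 0.0777 without 6 h and 0.0519 without 8 h, and KLF9 0.12 without 4 h, 0.129 without 6 h, 0.0947 without 8 h and 0.0778 without 10 h. Of the 10 falls named, 7 lost their call without 4 h, 8 without 6 h, 7 without 8 h and 3 without 10 h, with ZIC2 highest at adjusted p = 0.135 without 6 h, and those of IER3 and IER5L passed without any 1 treated culture.

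In new RNA 669 genes rose and 381 fell of 17507. FKBP5 rose by 3.93 ± 0.20 (adjusted p = 1.5e-05), TSC22D3 by 4.84 ± 0.28 (adjusted p = 2.4e-05), FGD4 by 4.21 ± 0.14 (adjusted p = 1.23e-06) and PER1 by 3.39 ± 0.18 (adjusted p = 1.59e-05). CIDEC, a lipid droplet gene, rose by 5.18 ± 0.40 (adjusted p = 0.000123). The other large rises were ETNK2 with 5.03, the glucose transporter gene SLC2A14 with 4.98 and RRAD with 4.87. Some genes had very few new counts at 0 h, and their ratios of treated to 0 h counts carry wide counting intervals. DNAJC15 had 1 count at 0 h and a 155-fold ratio (27.7 to 6130), SLC16A12 2 counts and 135-fold (37.4 to 1120), the cyclin-dependent kinase inhibitor gene CDKN1C 2 counts and 90.2-fold (24.9 to 746), the endothelin gene EDN3 2 counts and 58.6-fold (16.2 to 485), and the sodium channel gene SCNN1G 3 counts and 45.4-fold (15.5 to 221). TRIML2 fell by 2.78 ± 0.24 (adjusted p = 0.00022), EREG, which encodes an epidermal growth factor receptor ligand, by 2.37 ± 0.22 (adjusted p = 0.000374) and the chemokine gene CCL2 by 2.01 ± 0.35 (adjusted p = 0.0102). ST8SIA4 fell by 2.47, PDE1C by 2.33, NAV3 by 2.23, IER3 by 1.95, ENC1 by 1.89, NHS by 1.89 and NR5A2 by 1.88. NR3C1 had −0.43 ± 0.12 in new RNA (adjusted p = 0.0649), with adjusted p = 0.0223 without 2 h and 0.0414 without 10 h. Without the 2 h culture 1176 genes rose and 846 fell, and without 6 h 428 and 201, and 614 fell without a low-count filter. The calls of DNAJC15 (adjusted p = 0.0688), CDKN1C (0.0663), RRAD (0.0963), PDE1C (0.11), NAV3 (0.0654) and NHS (0.0948) were lost without 6 h. Some were also lost without 4 h, namely CDKN1C (0.0583), RRAD (0.0893), PDE1C (0.0936) and NHS (0.0793), without 8 h, namely RRAD (0.0771), PDE1C (0.0718), NAV3 (0.0511) and NHS (0.0691), and RRAD without 10 h (0.0593).

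Glucocorticoid-induced genes rose together: 18 of 36 measured members rose in whole RNA and 0 fell (31 rose adjusted over the list alone), with a median log2 fold of 1.79 (camera adjusted p = 1.27e-108, and adjusted p = 0.0436 with an estimated correlation). In new RNA 30 of 35 rose and 0 fell (32 adjusted over the list alone), with a median of 1.86 (adjusted p = 1.46e-116, and adjusted p = 0.0073 with an estimated correlation), CDKN1C, CIDEC, TSC22D3 and FKBP5 having the largest folds. Epithelial ion transport genes rose in new RNA, 6 of 11 up and 1 down (7 and 1 adjusted over the list alone), with SCNN1B at 3.85 ± 0.58 (adjusted p = 0.00433), SCNN1A at 2.86 ± 0.46 (adjusted p = 0.00605) and AQP3 at 2.76 (adjusted p = 0.0489), which with SCNN1G are channel genes. Their median was 0.60 (adjusted p = 6.92e-07, and adjusted p = 0.0592 with an estimated correlation). In whole RNA 0 of 12 passed over all genes (5 up and 1 down adjusted over the list alone), with a median of 0.44 (adjusted p = 0.00113, and adjusted p = 0.509 with an estimated correlation). Circadian clock genes had 4 of 16 up and 1 down in new RNA (4 and 1 adjusted over the list alone), with a median of 0.19 (adjusted p = 0.00668, and adjusted p = 0.425 with an estimated correlation). PER2 rose by 1.33 (adjusted p = 0.000414), NPAS2 fell by 1.36 (adjusted p = 0.021), and C1orf51 was at least 4.02-fold higher, with its 0 new counts at 0 h set to the floor of 3. The list median was the same with C1orf51 at that bound. In whole RNA 2 of 17 rose (4 up and 2 down adjusted over the list alone), with a median of 0.029, a mean of 0.60 and adjusted p = 0.0193 (0.509 with an estimated correlation). Without the 2 h culture the adjusted p was 0.126 in new and 0.0929 in whole RNA, and without 6 h 0.0559 in whole RNA.

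Inflammatory cytokine genes fell in new RNA, 5 of 12 down and 0 up (7 down adjusted over the list alone), with IL11 at −4.65 ± 0.49 (adjusted p = 0.000699), CCL2 at −2.01, the receptor gene PLAUR at −1.30 ± 0.16 (adjusted p = 0.00163) and IL8 at −1.59 (adjusted p = 0.303). The median was −1.12 (adjusted p = 5.77e-10, and adjusted p = 0.134 with an estimated correlation). In whole RNA 1 of 17 fell, which was IL11 at −4.05 (adjusted p = 0.0261), and 6 adjusted over the list alone, with a median of −0.89 (adjusted p = 3.49e-08, and adjusted p = 0.0436 with an estimated correlation). Immediate early genes split, with 4 of 27 up and 7 down in new RNA (4 and 8 adjusted over the list alone): IER3 and FOSL1 fell, IER2 fell by 1.74 (adjusted p = 0.00939) and the matrix-associated CTGF rose by 1.63 (adjusted p = 0.0384). The list's adjusted p was 0.0131 in new RNA with a median of −0.12, and 0.0308 in whole RNA with a median of −0.058, where 1 of 29 rose and 4 fell (4 and 8 adjusted over the list alone). These were adjusted p = 0.494 and 0.792 with an estimated correlation. Without the 2 h culture the list had adjusted p = 0.0699 in new and 0.0764 in whole RNA, and without 4 h 0.106 in whole RNA. NRF2 targets had 7 of 25 down and 1 up in new RNA (14 and 2 adjusted over the list alone), with a median of −0.39 (adjusted p = 3.34e-07, and adjusted p = 0.615 with an estimated correlation). The cystine transporter gene SLC7A11 fell by 1.39 (adjusted p = 0.048), the ferritin gene FTL by 1.14 ± 0.09 (adjusted p = 0.000178) and GCLM by 0.86 (adjusted p = 0.0453), OSGIN1 had −1.27 (adjusted p = 0.0507), and the other ferritin gene, FTH1, chosen after its value was seen, rose by 0.55. In whole RNA 0 of 25 passed, also adjusted over the list alone, with a median of −0.14 (adjusted p = 0.00623, and adjusted p = 0.792 with an estimated correlation).

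Heat shock genes had 3 of 13 down and 1 up in new RNA (9 and 3 adjusted over the list alone), with HSPB1 rising by 1.56 (adjusted p = 0.00336), HSPA1A at −0.95 (adjusted p = 0.0311), HSPA1B at −0.93 (adjusted p = 0.023) and HSP90AA1 at −0.75 (adjusted p = 0.0519). The list median was −0.33 (adjusted p = 0.0292, and adjusted p = 0.829 with an estimated correlation), with adjusted p = 0.13 without 2 h and 0.056 without 8 h. S-phase genes had 0 of 43 members past the threshold in either RNA, also adjusted over the list alone, with medians of −0.34 in new (adjusted p = 0.000117) and −0.19 in whole RNA (adjusted p = 0.000542). These were adjusted p = 0.829 and 0.808 with an estimated correlation. G2/M genes had 2 of 54 down in new RNA, HJURP at −0.61 (adjusted p = 0.033) and ECT2 at −0.39 (adjusted p = 0.0432), both chosen after their values were seen, 0 in whole RNA, and 0 in both adjusted over the list alone, with medians of −0.12 (adjusted p = 0.00962, and 0.0556 without 8 h) and −0.10 (adjusted p = 0.00243). The G2/M list had adjusted p = 0.829 in new and 0.808 in whole RNA with an estimated correlation. Ribosomal protein genes had 0 of 75 past the threshold in new RNA, also adjusted over the list alone, and a median of −0.079 (adjusted p = 0.0389, and adjusted p = 0.829 with an estimated correlation), with 0.165 without 6 h and 0.0837 without 8 h. Among lists that did not pass, p53 targets had 3 of 21 up and 1 down in new RNA (3 and 2 adjusted over the list alone), with GADD45A at 1.67 (adjusted p = 0.000215), TP53I3 at 1.61 (adjusted p = 0.000164) and CDKN1A at 1.09 (adjusted p = 0.000266) beside the fall of GDF15. Its median was −0.21, while the test pointed up (adjusted p = 0.732). Matrix and TGF-beta genes had 4 of 25 up and 1 down (5 and 2 adjusted over the list alone), with SNAI2 at 2.95 (adjusted p = 0.021). Epithelial junction genes had 3 of 16 up and 2 down (6 and 4 adjusted over the list alone), with the keratin gene KRT8 at 1.37 (adjusted p = 0.015) and CLDN2 at −2.44 (adjusted p = 0.023), and without 2 h the list had adjusted p = 0.0275. HEK293T markers had 0 members past the threshold, also adjusted over the list alone, with medians of −0.25 over 4 in new and −0.28 over 7 in whole RNA, where the list had adjusted p = 0.0775, and 0.0459 without 6 h. Over the lists, 8 passed in whole and 10 in new RNA, and 2 and 1 with an estimated correlation.

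Of genes tested in both, 128 rose in whole and in new RNA (of 134 and 669, with 5.12 expected for independent lists) and 49 fell in both (of 54 and 381, with 1.18 expected), though whole counts include the new ones. The test of new against pre-existing RNA had 0 calls of 22440 in edgeR, and DESeq2 called 8 higher and 5 lower in new RNA. In edgeR 1216 genes had an unadjusted p under 0.05, as a total near the number that chance alone gives at that threshold. The split was uneven, with 755 of them higher and 461 lower in new RNA. EdgeR called 128 higher and 55 lower without a low-count filter, and 22 higher and 14 lower without the 2 h culture. FKBP5 stood at a log2 fold of 3.62 in new RNA at 2 h and at 0.93 in pre-existing RNA, and at 3.92 and 3.79 by 10 h. TSC22D3 had 4.48 and 2.26 at 2 h and 5.09 and 4.53 at 10 h, and PER1 3.39 and 1.93, then 3.27 and 2.43. Over 32 glucocorticoid-induced genes the median was 1.66 in new and 1.02 in pre-existing RNA at 2 h, where new was above pre-existing in all 32, and 1.71 and 1.74 at 10 h, where it was above in 20. At 2 h the label and the treatment had lasted equally long, and pre-existing RNA, being whole minus called-new counts, also holds any new molecules that were not called, so its values need not be those of RNA made before the label. With 1 culture per time, no single time was tested.

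**Figure D2:**
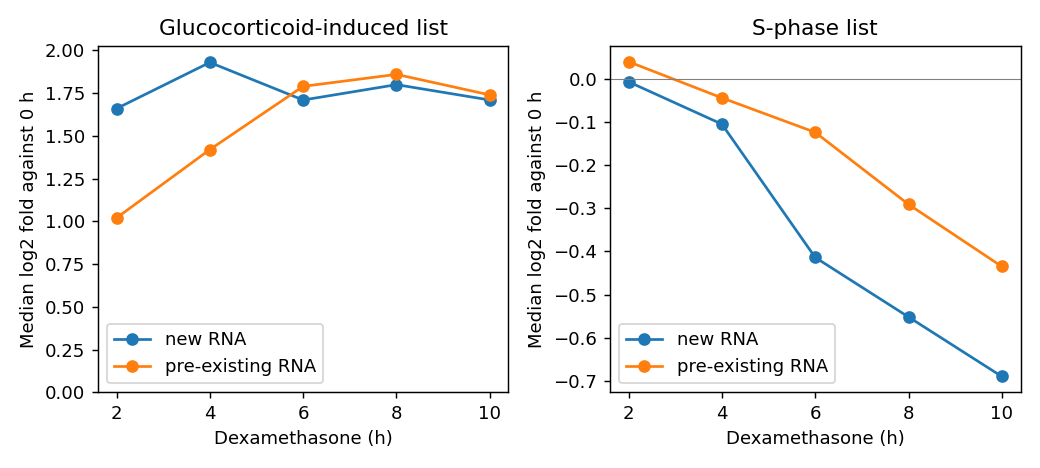
Median log2 fold against 0 h at each dexamethasone time of 32 glucocorticoid-induced and 43 S-phase genes, in new and in pre-existing RNA (whole minus called-new counts), with 1 culture per time. The glucocorticoid-induced median starts at 1.66 in new and 1.02 in pre-existing RNA, and the S-phase median ends at −0.69 in new and −0.43 in pre-existing RNA.

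Lists were also tested for slopes over the treated cultures, which was decided after the data were seen. S-phase genes, most of which act in DNA replication, declined with time. In new RNA 40 of 43 had a falling slope and 0 a rising one (42 adjusted over the list alone), led by GINS2 with −0.15 log2 units per hour (adjusted p = 0.00162), DTL −0.14 (adjusted p = 0.000324), CDC45 −0.13 (adjusted p = 0.00693) and CLSPN −0.13 (adjusted p = 0.00063). The median slope was −0.099 (adjusted p = 9.69e-51, and adjusted p = 0.226 with an estimated correlation). In whole RNA 39 fell and 0 rose (41 adjusted over the list alone), with a median of −0.072 (adjusted p = 7.83e-46, and adjusted p = 0.0971 with an estimated correlation). G2/M genes fell in 33 of 54 in whole RNA (46 adjusted over the list alone), with a median of −0.032 (adjusted p = 2.74e-15, and adjusted p = 0.0838 with an estimated correlation), and in 13 in new RNA (29 adjusted over the list alone). Heat shock genes had 10 of 13 falling and 1 rising in whole RNA, as adjusted over the list alone, with HSPA1B at −0.12 (adjusted p = 0.000301) and HSPB1 at 0.18 (adjusted p = 1.46e-05), and a median of −0.049 (adjusted p = 4.5e-07, and adjusted p = 0.0971 with an estimated correlation). Glucocorticoid-induced genes rose further in whole RNA, 16 of 35 (20 up and 2 down adjusted over the list alone), with CDKN1C at 0.37 (adjusted p = 0.0224) and the metallothionein genes MT1X at 0.36 (adjusted p = 3.18e-05) and MT2A at 0.34 (adjusted p = 3.18e-05). Their median was 0.067 (adjusted p = 3.84e-19, and adjusted p = 0.269 with an estimated correlation).

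The largest rising slopes in new RNA were those of the complement gene C3 with 0.32 (adjusted p = 0.00395), MAOA 0.28 (adjusted p = 0.000963), GPR1 0.25, ANKRD1 0.25 and DNAJC15 0.23, and the largest falling ones FSTL4 −0.56 (adjusted p = 3.5e-05), SOX6 −0.54 (adjusted p = 0.0156), PDE1C −0.27, NR0B1 −0.23 and BACH2 −0.22. In whole RNA the acute phase gene SAA1 rose by 0.59 per hour (adjusted p = 0.000188), LRRC36 by 0.57, SDS by 0.54, the cadherin gene CDH16 by 0.52 and SFRP5 by 0.47, and S100Z fell by 0.74 (adjusted p = 0.00646), BCL2A1 by 0.41, DNAH9 by 0.39 and SOX6 by 0.29. Slopes run over the treated cultures only, so a falling slope need not mean a level below 0 h. Against 0 h, the treated log2 fold in whole RNA was 2.95 ± 2.53 (SE) for S100Z, 1.38 ± 1.41 for DNAH9, 0.92 ± 1.12 for SOX6 and −1.38 ± 0.90 for BCL2A1. For new RNA it was 0.11 ± 1.15 for FSTL4, 2.61 ± 2.01 for SOX6 and 0.63 ± 0.57 for BACH2. PDE1C had −2.33 ± 0.55 and NR0B1 −1.47 ± 0.535. In new RNA CDH16 was at least 16.5-fold higher in treated cultures, with 0 counts at 0 h set to the floor of 3. In all, 571 genes rose and 668 fell with time of 14463 in new RNA, and 1327 rose and 1389 fell of 18955 in whole RNA. The total in new RNA became 461 without 8 h and 622 without 10 h, and in whole RNA 1596 without 2 h, 1326 without 8 h and 1740 without 10 h.

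Most treated A549 cells scored above the cells at 0 h for glucocorticoid-induced genes. In new RNA 3.94% of cells at 0 h lay above the 95th percentile of 0 h cells, 13 counts per 2700, and 84.9% (82.6 to 87.0) did at 2 h, 88.2% at 4 h, 88.5% at 6 h, 90.2% at 8 h and 91.5% (89.9 to 92.9) at 10 h. In whole RNA the threshold was 23 counts per 15500, and the shares were 4.66% at 0 h, 83.2% (80.8 to 85.3) at 2 h, 94.3% at 4 h, 98.7% at 6 h, 99.3% at 8 h and 99.7% (99.2 to 99.9) at 10 h. The median cell had 6 new counts on these genes at 0 h, 21 at 2 h and 23 at 10 h, and 12, 33 and 65 whole counts. Cells are not replicates, so no test was made.

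Cells with a high S-phase score made up less of the later cultures, and cells low in both scores more. The S-high share was 38.2% (35.2 to 41.3) at 0 h, 39.5% at 2 h, 35.7% at 4 h, 29.5% at 6 h, 21.9% at 8 h and 18.2% (16.1 to 20.4) at 10 h. Low cells made up 27.8% (25.1 to 30.7) at 0 h and 51.8% (49.0 to 54.5) at 10 h, and G2M-high cells 34.0% (31.1 to 36.9) and 30.03% (27.6 to 32.6). Pooled over the 6 cultures, new counts were 22.8% of all counts in low, 20.9% in S-high and 20.1% in G2M-high cells, and they came in this order within each culture. For G2/M genes not used to set the classes, 23.9% of counts were new in S-high cells, 16.4% in G2M-high and 11.5% in low cells, also in this order within each culture. For such S-phase genes the pooled shares were 21.6%, 18.0% and 22.3%, and low cells were below S-high cells at 6 h (21.3% and 22.8%) and 8 h (19.6% and 21.8%). Classes are ranges of a score, 6671 cells were kept and 552 lay within 0.1 of the threshold. These intervals cover counting error only.

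**Figure D3:**
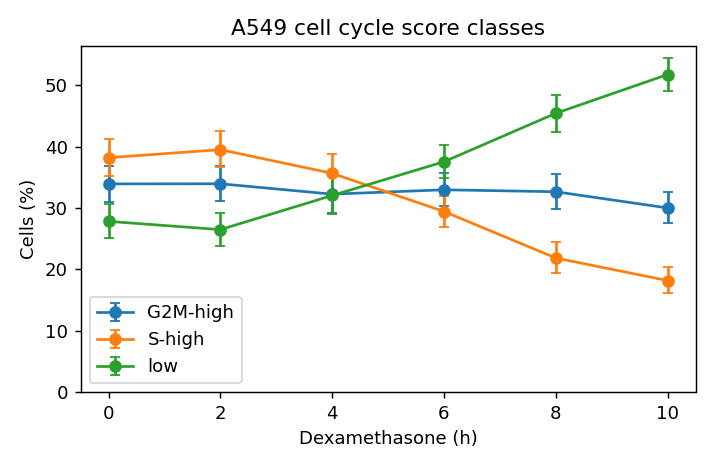
Percent of A549 cells called S-high, G2M-high or low at each dexamethasone time, with exact 95% binomial error bars for counting error. The S-high share goes from 38.2% at 0 h to 18.2% at 10 h and the low share from 27.8% to 51.8%.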

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

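Of the tests below, that of weaker labelling, that of gene span and the simulated uniform fall were chosen after the result was seen.

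In new RNA, S-phase genes fell from 2 to 10 h, by a median of 0.687 on the log2 scale over genes not used to set the classes in the cells kept for them. Weaker labelling or conversion at late times is argued against, since whole RNA, which does not depend on the label, had a median of −0.553 (−0.601 to −0.475). Fewer S-high cells is a candidate explanation: their share at 10 h was 0.461 of that at 2 h, and within S-high cells the median was −0.085 (−0.116 to −0.014). In simulated 2 h cells with every S-phase gene lowered alike, the median within S-high cells was −0.483 (−0.536 to −0.432) and the S-high share 9.65%. The simulation lowered whole counts, which set the classes, by the 0.687 of new RNA. Whole RNA fell less, so the simulated share is likely too low. S-high is itself a cut on S-phase counts, so a smaller share of such cells partly restates the fall. No untreated culture was set beside each later time, so dexamethasone and time in culture stay open as reasons.

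Far more genes passed in whole RNA without the 2 h culture. Of the 1600 genes then called, those with few counts at 0 h or a small mean change were left out, and the 2 h log2 fold was 0.453 (0.433 to 0.474) of the mean of 4 to 10 h in whole RNA over 1310 genes and 0.797 (0.77 to 0.823) in new RNA over 1274. With each other treated culture left out, over the genes then called, its ratio ran from 0.945 to 1.06 in whole and 0.918 to 1.07 in new RNA. These ratios rest on only 64 to 132 genes in whole and 63 to 131 in new RNA. Those genes passed with the 2 h culture in the fit, so the ratios are not a like comparison for 2 h. A lag of accumulated RNA behind synthesis asked for a new RNA ratio above 0.8 and a 2 h culture apart for technical reasons for one under 0.67. The interval spans the first bound and lies above the second, so the ratio asked of a technical difference was not met. The explanations still cannot be told apart, since the new RNA ratio was not above 0.8 over its interval and there is 1 culture per time.

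Gene groups differed in new RNA share in A549, and longer genes had higher shares, with a Spearman rho across genes of 0.438. Short-lived regulators stood at percentile 100.0 among random lists matched on expression and span. This cannot decide on span, since matching moved the central random range further below them, from 15.9% to 35.0% down to 7.81% to 18.8%. For ribosomal protein genes matching moved that range towards their median of 5.95%, from 10.5% to 17.2% down to 6.41% to 8.57%. They stayed at percentile 0.31, which argues against gene span as the whole reason for that list. Cholesterol synthesis genes went from percentile 1.06 to 24.3, so span stays open for them. No biological explanation was tested for this pattern.

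Among the 5 treated cultures some list medians stood apart from the other times. Immediate early genes in new RNA had a median log2 fold of −0.558 at 2 h, against −0.196 to −0.071 at the other times. Cholesterol synthesis genes in whole RNA had 0.247 at 10 h, against 0.0247 to 0.0855. For 3 lung secretory genes new RNA had −0.131 at 4 h, against −0.385 to −0.312, and pre-existing RNA had −0.0811 at 2 h, against 0.117 to 0.183. Actin cytoskeleton genes in whole RNA had 0.068 at 10 h, against 0.0103 to 0.0268. In all 5 of 78 groups stood apart, and chance alone gives about 1 in 20, or 3.9.

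Mixture cells that the annotation puts in no labelling group had more new RNA than the background of their line. The 53 HEK293T cells had 18.8% new counts (18.3 to 19.3), with 18 cells above 10%, and the 42 NIH/3T3 cells 14.4% (13.9 to 14.9), with 15 cells above 10%. Their median cells had 2.98% and 1.77%, and held 370 and 504 counts, against 6720 and 6731 in labelled cells of the lines.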

How the results depend on the processing

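All alternatives were planned. No paired analysis was possible because no label pairs the cultures. The alternative without mitochondrially encoded genes gave no value for A549, whose matrix holds none. No result reversed. Of the values of named genes under the alternatives, 391 kept their side of the threshold, 6 passed it and 53 no longer did, and for lists 293, 3 and 26. Counts of calls moved by over 1.5 times, or shares and correlations by more than their interval's margin for counting error or resampled genes, 81 times, and by less 99 times. Where no value below shows it, the cause was not tested.

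Without a low-count filter 302 genes rose and 149 fell in whole RNA, 614 fell in new RNA, and 128 were higher and 55 lower in new than in pre-existing RNA. DESeq2 gave 557 up and 229 down in whole RNA, and 8 higher and 5 lower in new than in pre-existing RNA. With each treated culture left out in turn, whole RNA rises ran from 57 to 931 and falls from 18 to 669, new RNA rises from 428 to 1176 and falls from 201 to 846, higher in new than pre-existing from 0 to 22 and lower from 0 to 14, slopes in new RNA from 461 to 1161 and in whole RNA from 1326 to 2525. With an estimated correlation 2 lists passed in whole and 1 in new RNA.

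The labelled HEK293T share was 54.1% as a median over cells, 54.3% over protein-coding genes and 54.6% without mitochondrially encoded genes, and the NIH/3T3 share 42.0% and 36.8% under the last 2 of these. The A549 share as a median over cells was 19.8%, 19.6%, 19.1%, 21.4%, 21.04% and 20.5% from 0 to 10 h, and over protein-coding genes 20.5%, 19.98%, 20.03%, 22.3%, 21.5% and 20.7%. With a minimum of 200 counts the rho was 0.744 for HEK293T and NIH/3T3 and 0.86 for HEK293T and A549, and at 0 h alone the latter was 0.941. Unthinned, the glucocorticoid score gave 89.5%, 91.8%, 93.8%, 94.0% and 95.4% of cells in new RNA from 2 to 10 h, and 96.6% in whole RNA at 4 h.

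At a threshold of 0.25, S-high cells were 43.1%, 44.7%, 40.5%, 33.3%, 25.9% and 21.1% from 0 to 10 h, and G2M-high cells 38.4%, 37.6%, 36.9%, 36.9%, 37.8% and 34.8%. At a threshold of 1, S-high cells were 23.1%, 25.3%, 22.2%, 18.2%, 13.1% and 10.8%, and G2M-high cells 18.5%, 19.7%, 16.7%, 17.9%, 15.3% and 13.6%. Depth limits the folds of genes with few new counts at 0 h, and 1 culture per time limits every test.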

Other observations

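The tests of lists for slopes were chosen after the data were seen, and the test of the hypothesis was written before its result was seen. In whole RNA, ion transport genes rose with time in 7 of 12 members and fell in 0 (9 up and 1 down adjusted over the list alone), with a median slope of 0.057 per hour (adjusted p = 2.13e-07, and adjusted p = 0.243 with an estimated correlation). Cholesterol synthesis genes rose in 8 of 23 and fell in 0 (9 and 0 adjusted over the list alone), with a median of 0.026 (adjusted p = 1e-04, and adjusted p = 0.32 with an estimated correlation). NRF2 targets fell in 12 of 25 and rose in 3 (15 and 5 adjusted over the list alone), with a median of −0.032 (adjusted p = 0.00276, and adjusted p = 0.567 with an estimated correlation). In new RNA, actin cytoskeleton genes rose in 6 of 18 (7 adjusted over the list alone), with a median of 0.045 (adjusted p = 3.65e-06, and adjusted p = 0.416 with an estimated correlation).

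The hypothesis that the rise of glucocorticoid-induced genes in new RNA differs between cell cycle classes was tested over 34 genes. The median fold on the log2 scale was 1.72 over 35 genes in low cells, and 1.87 in S-high and 1.98 in G2M-high cells over 34. The median difference of G2M-high and low cells was 0.222 (bootstrap interval over genes 0.0537 to 0.384), and that of S-high and low cells −0.023 (−0.168 to 0.132), the 2 contrasts computed. The first contrast goes with a larger rise in G2M-high cells, but class and time were not separated, genes are not replicates and each time is 1 culture.

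The 46 labelled mixture cells called as both species had 43.1% new counts, between the shares of the lines. The 3 such cells without a labelling group had 1.103%.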
